A study of Homo sapiens with 6 samples.

How the data were processed

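RNA sequencing was performed on CAL-62, an established human cell line derived from an anaplastic thyroid carcinoma, in 3 cultures carrying an empty vector and 3 cultures overexpressing FOXK2, a forkhead transcription factor. The series design text calls the 3 samples of each group biological replicates, without saying how the cultures were separated, so p-values measure the spread between these samples. Per the labels' protocols, libraries were made from total RNA with a stranded kit that fragments RNA, primes it at random and marks the second strand with dUTP. Per the submitters' processing notes, reads were handled with cutadapt, HISAT2 2.1.0 and StringTie on the human genome build hg19. The role and settings of each tool, and whether the strand was used in assigning reads, are not given in the sources used here.

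The deposited table holds 31009 transcripts in 6 columns, 1 per library. Its values were taken as FPKM because the submitters' processing notes name StringTie; the header of the deposited table gives no unit. Were the values TPM, each library would differ from FPKM by 1 factor, which the scaling alternative named below covers. Every listed transcript had a mean of at least 0.5 in one group or the other, so transcripts below that in both groups, and their part of a gene's sum, were not analysed here. No read counts are in the table. For genes with 1 listed transcript, the 200 lowest products of value and transcript length in vector replicate 1 were divided by the smallest of them. Whole multiples, within a tolerance of 0.02, made up 7.5% of cases, and no common step was estimated. The sequencing depth is unknown, so no counting interval is given. A value of exactly 0 in some library was listed for 5455 transcripts, reaching 160 FPKM in another library, so a 0 is reported only as listed at 0.

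Transcript identifiers carry the suffixes of an annotation carried over to hg19, and the annotation used here for names, GENCODE 29, is on another build. It was therefore used for gene names, GC content and transcript length only, and no coordinates are printed. Of the listed transcripts, 30893 were matched and 116, with 0.211% of the summed signal, were not. Matched transcripts were summed to 11359 genes, of which 3916 had 1 listed transcript. Genes with near-identical copies (the CXCL1, CXCL2 and CXCL3 chemokines, SAA1 and SAA2, HLA genes, metallothioneins, histones and ribosomal proteins) are uncertain, because the division of their shared reads is not known.

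Gene sums were tested on the log2(FPKM + 1) scale with limma 3.58.1 in R 4.3.3 (a linear model with 1 term for the group and moderated variances with an intensity trend, two-sided), on genes with a mean of at least 1 FPKM over the 6 libraries. The Benjamini-Hochberg adjusted p-value had to lie under 0.05. Fold changes are differences of group means on this scale, FOXK2 overexpression minus vector, and understate the change of genes with low values. Transcripts were tested in the same way as deposited. Gene lists with at least 5 measured members were tested with camera at a preset inter-gene correlation of 0.01, which compares a list with all other genes, and with camera at an estimated correlation. The fry test was added, which asks whether the genes of a list move, on balance, one way. All 3 were adjusted over the tested lists. Means are given with the SD of 3 libraries.

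The groups, tests, 34 gene lists, alternatives and the rule for naming genes were set before the data were examined, except where stated. Genes named are FOXK2, FOXK1, VEGFA, FLT1 and KDR; the 12 with the largest rise and the 12 with the largest fall among genes past the threshold, with a mean of at least 1 FPKM in a group and no overlap between the groups' values; up to 4 members of smallest p in each list; and the transcripts of FOXK2 and VEGFA with up to 5 genes whose transcripts were called in opposite directions. Some genes that this rule takes are not reported here.

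Alternatives were pseudocounts of 0.1 and 0.5, no filter on low values or a minimum mean of 5 FPKM, quantile normalization, median ratio scaling, no intensity trend, limma array weights, the replicate number as a block, each library left out in turn, the most abundant transcript in place of the gene sum, and, for the counts of genes and transcripts only, a log2 fold change of at least 1 beside the adjusted p. A GC and length correction, in which each library's smooth trend on GC content and log length (natural splines with 4 degrees of freedom) was removed from its deviations, was added after a trend with GC content had been seen in the data.

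The scripts were tested on simulated data made from the real means and spreads of the 10305 tested genes. Of 100 genes changed 2-fold, 63% were recovered, and of 100 changed 4-fold, 86%. No gene was called in the wrong direction, and 6.29% of the calls were unchanged genes. The noise was drawn independently for each gene and library, so this share does not carry over to real libraries whose genes share a trend. With a simulated GC trend, 619 unchanged genes were called without the correction and 10 with it. That trend was linear in GC content, and no simulated change in expression followed GC content. The simulation therefore does not show whether the correction removes a real change of that kind.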

Results

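The transcriptome of CAL-62 anaplastic thyroid cancer cells was measured by RNA sequencing in 3 cultures overexpressing FOXK2 and 3 cultures carrying an empty vector. The title of the series names VEGFA as a gene activated by FOXK2 and apatinib, an inhibitor of VEGF receptor signalling, as the drug to which cells become resistant. No drug was named in the sample labels. The summed FPKM per library was 370457, 376120 and 395782 in vector replicates 1, 2 and 3, and 335151, 363133 and 347308 in the FOXK2 replicates. The number of reads behind these values is unknown. Between 10070 and 10263 genes exceeded 1 FPKM in each library. Across genes, which are not independent replicates, log2 values correlated at 0.975 to 0.979 between vector libraries, at 0.956 to 0.976 between FOXK2 libraries and at 0.873 to 0.941 between the groups. FOXK2 replicate 2 was the FOXK2 library nearest to the vector libraries, with correlations of 0.931 to 0.941.

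FOXK2 mRNA was higher in every FOXK2 library than in every vector library. Its level was 15.9 ± 3.17 FPKM in vector cells and 32.4 ± 3.31 FPKM in FOXK2 cells (SD, n = 3), a log2 fold change of 1.00 (SE 0.17, limma adjusted p = 0.00525). Most of the signal came from transcript ENST00000335255, which rose from 14.4 ± 2.72 to 30.3 ± 3.22 FPKM (log2 fold change 1.03, SE 0.18, limma adjusted p = 0.0291). The second listed transcript, ENST00000575578, was not called (log2 fold change 0.37, limma adjusted p = 0.397). The table does not separate transgene from endogenous reads. The paralog FOXK1 stood at 5.64 ± 0.399 and 5.16 ± 0.501 FPKM, with no call (log2 fold change -0.11, SE 0.14, limma adjusted p = 0.568; 0.12, adjusted p = 0.400 with the GC and length correction).

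VEGFA, the ligand of the receptors encoded by FLT1 and KDR, was also higher in all 3 FOXK2 libraries than in any vector library. Its level rose from 9.66 ± 1.35 to 16.5 ± 1.79 FPKM (SD, n = 3), a log2 fold change of 0.72 (SE 0.15, limma adjusted p = 0.0117). The most abundant of its 9 listed transcripts, ENST00000372067, stood at 3.80 ± 0.527 and 7.03 ± 2.1 FPKM, which did not pass the test across transcripts (log2 fold change 0.72, SE 0.23, limma adjusted p = 0.117). With the most abundant transcript of each gene in place of the gene sum, VEGFA was likewise not called (adjusted p = 0.0694, against a range from 0.000142 to 0.0474 over the other alternatives). None of the 4 tested VEGFA transcripts was called (log2 fold changes from -0.09 to 0.75, limma adjusted p from 0.117 to 0.851). Of the 18.3 FPKM of VEGFA in FOXK2 replicate 2, 7.06 came from ENST00000523950. That transcript was listed at 0.0424 and 0.768 FPKM in FOXK2 replicates 1 and 3, and at 1.89, 0.0525 and 0.0195 FPKM in the vector libraries. Without FOXK2 replicate 2 the VEGFA sum was still called (log2 fold change 0.64, limma adjusted p = 0.0180). FLT1 and KDR, the genes of VEGF receptors 1 and 2, were not among the listed transcripts and were not analysed here. Of 10 genes fixed as VEGF ligands and receptors, 6 were measured. VEGFA and the coreceptor NRP2 rose (NRP2 from 10.6 ± 0.930 to 20.2 ± 2.49 FPKM, log2 fold change 0.87, limma adjusted p = 0.00466), and none of the 6 fell, against 2 that rose and 1 that fell when adjusted over the list alone. VEGFB (log2 fold change -0.44, limma adjusted p = 0.0555) and PGF (0.45, adjusted p = 0.0838) missed the threshold. With the GC and length correction PGF was called (1.01, adjusted p = 0.00441), and VEGFB had the opposite sign and no call (0.23, adjusted p = 0.0590). As a set the list did not pass against other genes (median 0.58, camera adjusted p = 0.30), while fry, which makes no such comparison, gave an adjusted p of 0.0147. With the correction it passed camera at the preset correlation (median 0.75, adjusted p = 0.0309) but not at an estimated correlation (adjusted p = 0.391).

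**Figure D1:**
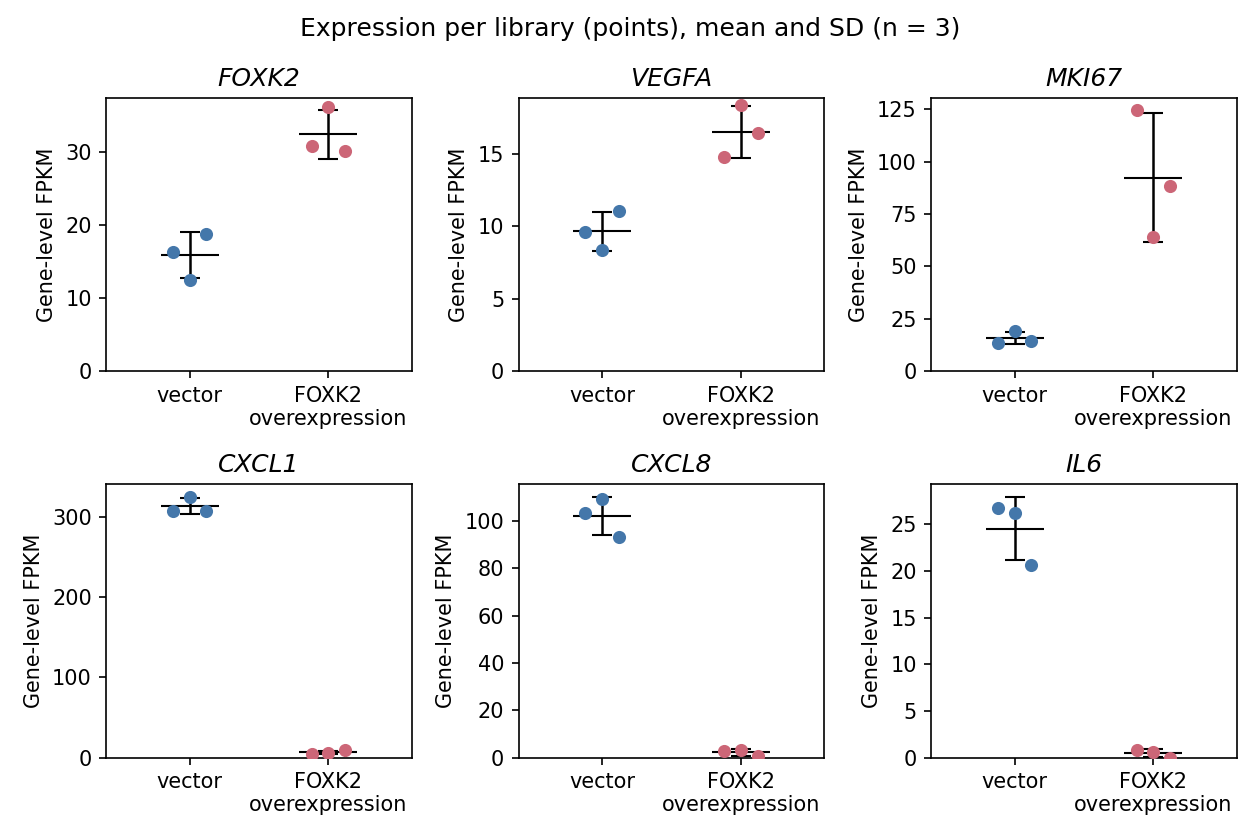
Gene-level FPKM of 6 genes in each library (points) with the mean and SD of 3 libraries per group (lines); every panel starts at 0 FPKM. FOXK2, VEGFA and MKI67 lie higher in all 3 FOXK2 libraries than in any vector library, and CXCL1, CXCL8 and IL6 lie lower, with CXCL1 at 313 FPKM in vector cells and 6.56 FPKM in FOXK2 cells on average.

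FOXK2 overexpression went with broad changes in expression. Of 10305 genes tested, 3741 (36.3%) differed between the groups, 1812 higher and 1929 lower in FOXK2 cells. A change of at least 2-fold was reached by 458 of the higher and 582 of the lower genes. In 5361 genes (52.0%) the values of the groups did not overlap, where chance gives 10%. The count varied with the libraries included. It was 2583, 2289 and 2018 without vector replicates 1, 2 and 3, and 2349, 4767 and 1944 without FOXK2 replicates 1, 2 and 3. It was 7117 with limma array weights, whose estimation stopped before convergence, and 2143 with the most abundant transcript of each gene.

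The 3 largest falls were those of CXCL1, LTB and CXCL8. CXCL1, a neutrophil-attracting chemokine, fell from 313 ± 10.0 to 6.56 ± 2.27 FPKM (SD, n = 3; log2 fold change -5.42, SE 0.20, limma adjusted p = 1.25e-05). CXCL8 fell from 102 ± 8.02 to 2.32 ± 1.46 FPKM (log2 fold change -5.08, SE 0.34, limma adjusted p = 0.000175), and CXCL2 from 32.3 ± 3.61 to 0.831 ± 0.0829 FPKM. The cytokines LTB, CSF2 and IL6 fell from 47.0 ± 21.1, 38.7 ± 8.32 and 24.5 ± 3.37 FPKM to 0.331 ± 0.265, 0.378 ± 0.0995 and 0.466 ± 0.419 FPKM. Complement component C3 fell from 22.1 ± 2.38 to 0.0152 ± 0.00127 FPKM (log2 fold change -4.51, SE 0.15, limma adjusted p = 1.25e-05). The complement factor gene CFB had a vector mean of 19.4 FPKM and was listed at 0.285, 0 and 0 FPKM in the FOXK2 libraries. The acute-phase gene SAA1 had a vector mean of 33.1 FPKM and was listed at 0.173, 0 and 0.371 FPKM. SLPI, a secreted protease inhibitor, fell from 206 ± 21.8 to 10.6 ± 2.92 FPKM, and C15orf48 from 38.1 ± 5.11 to 0.243 ± 0.247 FPKM. CDKN1C, an inhibitor of cyclin-dependent kinases, fell from 60.6 ± 15.3 to 1.79 ± 0.276 FPKM (log2 fold change -4.44, SE 0.20, limma adjusted p = 2.81e-05). The split of reads between CXCL1 and CXCL2, and between SAA1 and its near-identical copy, is uncertain.

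The 12 largest rises included MKI67 and CENPE. MKI67, a marker of cycling cells, rose from 15.8 ± 2.96 to 92.4 ± 30.5 FPKM (SD, n = 3; log2 fold change 2.44, SE 0.25, limma adjusted p = 0.00081). The spindle, kinetochore and cytokinesis genes ASPM, DLGAP5, CENPE, CEP55 and ECT2 rose with log2 fold changes of 2.38, 2.38, 2.25, 2.30 and 2.29. DCK, a kinase of nucleoside salvage, rose from 2.67 ± 1.15 to 19.0 ± 2.87 FPKM, and the condensin subunit gene SMC2 from 12.2 ± 4.85 to 59.7 ± 18.2 FPKM. The largest rise was that of CAMK2N1, an inhibitor of CaM kinase II, from 7.46 ± 1.63 to 61.3 ± 11.9 FPKM (log2 fold change 2.88, SE 0.20, limma adjusted p = 0.000182). VEPH1 and EFNB2, which encodes ephrin-B2, rose from 5.65 ± 0.754 and 4.23 ± 0.746 FPKM to 35.1 ± 9.38 and 24.4 ± 3.26 FPKM. Adjusted p-values of the 12 largest rises lay between 0.000182 and 0.00365. With the most abundant transcript of each gene, SMC2 (log2 fold change 3.02, adjusted p = 0.0870) was not called.

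The difference between the groups followed the GC content of the transcripts. Across genes, which are not independent replicates, the Spearman correlation of the log2 fold change with GC content was -0.587, and that with length 0.332. GC content and length together accounted for 32.3% of the variance of the log2 fold change. When genes were divided into 10 bins of GC content, in the lowest (median 37.9%), 362 genes rose and 28 fell, and in the highest (median 64.5%), 21 rose and 455 fell. The slope on GC content, in log2 units per 10 percentage points, was 0.147, 0.153 and 0.266 in the vector libraries and -0.342, -0.00883 and -0.215 in the FOXK2 libraries. With the GC and length correction 3102 genes differed, 1622 higher and 1480 lower in FOXK2 cells. These included 2121 of the 3741 genes called without it, and 3 others of them were called in the opposite direction. All 24 of the genes with the largest rises and falls, FOXK2 (log2 fold change 1.14) and VEGFA (0.97) remained called with the correction.

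**Figure D2:**
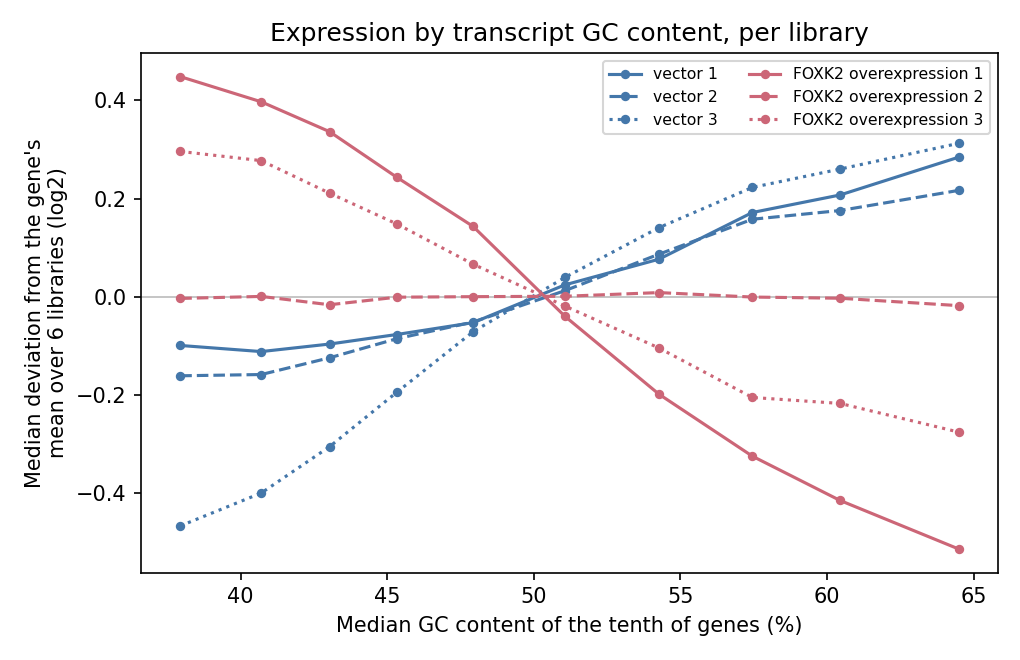
Median deviation of each library (lines; vector in blue, FOXK2 overexpression in red) from the 6-library mean of each gene, on the log2 scale, for 10 equal bins of the tested genes ordered by GC content (median GC content in percent on the x axis). In the bin with the highest GC content the vector libraries lie at 0.284, 0.217 and 0.313 and the FOXK2 libraries at -0.514, -0.0182 and -0.276.

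Of 34 lists fixed before the data were examined, 30 had enough measured members for a test and 4 passed it. NF-kB-driven cytokines and regulators fell: 14 of 15 measured members fell and none rose (15 and 0 adjusted over the list alone), with a median log2 fold change of -2.92 (camera adjusted p = 1.46e-14, fry adjusted p = 2.7e-05). The call was not made with an estimated correlation (adjusted p = 0.0713). CXCL3 fell from 13.7 ± 0.690 to 0.156 ± 0.0766 FPKM. Interferon-stimulated genes fell in 15 of 21 members, with none rising (16 and 0 adjusted over the list alone; median -1.22, camera adjusted p = 2.08e-08, fry adjusted p = 0.00587). That list did not pass with an estimated correlation (adjusted p = 0.584). Among its members MX1, an antiviral GTPase, fell from 28.6 ± 7.23 to 4.33 ± 0.610 FPKM, OAS1, a sensor of double-stranded RNA, from 7.04 ± 2.93 to 0.25 ± 0.0904 FPKM and IRF7 from 11.0 ± 1.55 to 2.69 ± 0.237 FPKM. In DNA replication and mitosis, 22 of 28 members rose and 1 fell (23 and 1 adjusted over the list alone; median 1.05, camera adjusted p = 4.49e-11, fry adjusted p = 2.7e-05), a call kept with an estimated correlation (adjusted p = 0.0422). The mitotic cyclin genes CCNB1 and CCNB2 rose from 62.3 ± 1.34 and 24.9 ± 0.748 to 178 ± 8.59 and 86.7 ± 3.24 FPKM, and AURKA and TPX2 had log2 fold changes of 1.75 and 1.67. The member that fell, cyclin E1 (CCNE1), which acts at entry into S phase and was chosen here after its values were seen, had a log2 fold change of -0.71 (limma adjusted p = 0.0080). The 5 members without a call, also named after their values were seen, were MCM2, MCM5, MCM7, CCNE2 and E2F1. The called MCM genes MCM3, MCM4 and MCM6 had log2 fold changes of 0.59, 0.51 and 0.84, below the list median. Cytosolic ribosomal protein genes fell in 16 of 35 members and rose in none (the same numbers adjusted over the list alone; median -0.42, camera adjusted p = 7.2e-05, fry adjusted p = 0.0366). The call was lost with an estimated correlation (adjusted p = 0.584), with the GC and length correction (median -0.07, adjusted p = 0.474; 3 members rose and 6 fell) and with quantile normalization (median -0.18, adjusted p = 0.118). RPS12 and RPLP1 fell from 440 ± 29.3 and 769 ± 70.6 to 274 ± 37.6 and 504 ± 62.1 FPKM.

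With the GC and length correction the medians were -3.09, -1.13 and 1.07 for the NF-kB, interferon and mitosis lists (camera adjusted p = 1.51e-15, 6.48e-10 and 1.57e-13 at the preset correlation). At an estimated correlation none of the lists passed in the corrected fit (adjusted p = 0.111, 0.391 and 0.111 for these 3). In that fit 20 interferon-stimulated genes fell.

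**Figure D3:**
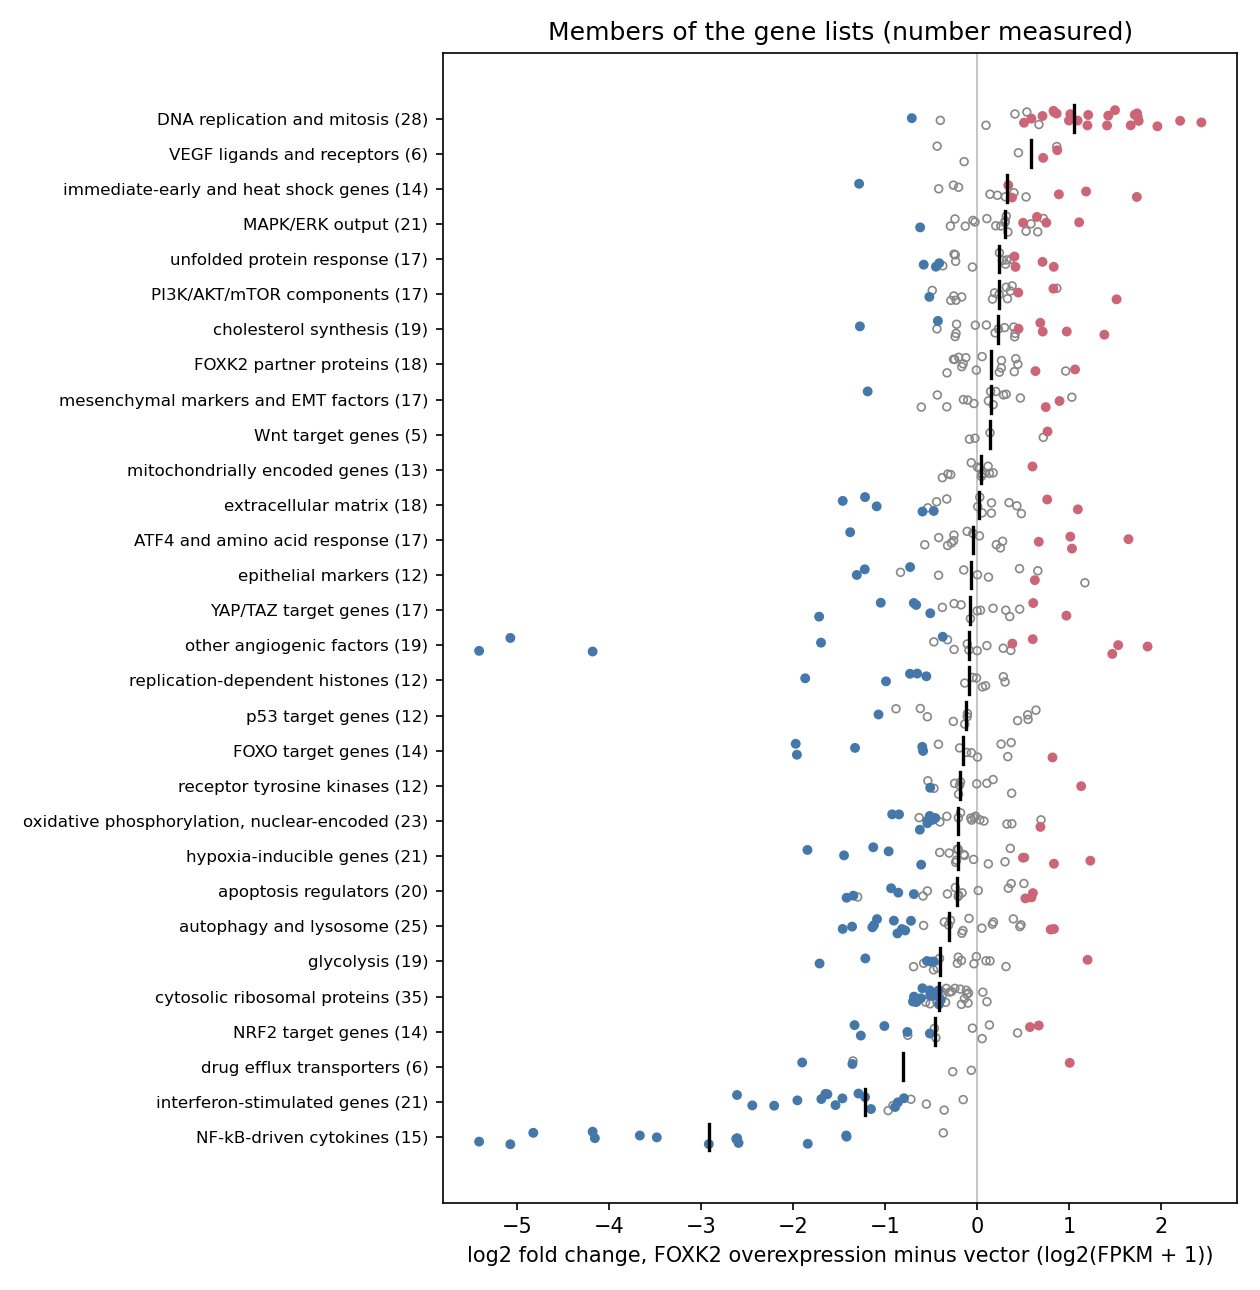
Log2 fold change (FOXK2 overexpression minus vector, on log2(FPKM + 1)) of each measured member of the tested lists, with the number measured in brackets. Filled points passed the test across all genes (red higher, blue lower), open points did not, and vertical bars are list medians, from -2.92 for the NF-kB list to 1.05 for DNA replication and mitosis.

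The other 26 tested lists did not pass camera (adjusted p from 0.101 to 0.841), and most held members that moved in both directions. Of these, 17 passed fry, which does not compare a list with other genes, among them autophagy and lysosome (down, adjusted p = 0.00361), MAPK/ERK output (up, adjusted p = 0.00464), other angiogenic factors (down, adjusted p = 0.00464), drug efflux transporters (down, adjusted p = 0.00464) and FOXO target genes (down, adjusted p = 0.00803). Other angiogenic factors had 5 of 19 members higher and 5 lower (the same adjusted over the list alone; median -0.09, -0.04 with quantile normalization and 0.05 with the GC and length correction). PDGFB, a growth factor for pericytes, rose from 4.15 ± 0.533 to 13.9 ± 0.901 FPKM (log2 fold change 1.53, limma adjusted p = 0.000673), while the falling members included CXCL1, CXCL2 and CXCL8, which also belong to the NF-kB list. Among 21 hypoxia-inducible genes 3 rose and 5 fell (the same adjusted over the list alone, median -0.21). EPAS1, which encodes HIF-2alpha, fell from 15.9 ± 5.56 to 3.62 ± 0.954 FPKM, DDIT4 from 32.7 ± 7.03 to 11.2 ± 0.209 FPKM, and BHLHE40 rose from 23.7 ± 2.19 to 43.1 ± 4.16 FPKM. Of 19 glycolysis genes 1 rose and 5 fell (the same adjusted over the list alone; median -0.41, -0.22 with quantile normalization and -0.11 with the GC and length correction): hexokinase 2 (HK2) rose from 1.52 ± 0.344 to 4.79 ± 0.757 FPKM and the lactate transporter gene SLC16A3 fell from 17.8 ± 0.663 to 4.79 ± 0.993 FPKM. Nuclear genes of oxidative phosphorylation had 1 of 23 members higher and 8 lower (1 and 9 adjusted over the list alone; median -0.20, -0.08 with quantile normalization and -0.09 with the GC and length correction), with COX5B falling from 294 ± 20.9 to 156 ± 30.2 FPKM. Among 13 mitochondrially encoded genes 1, MT-ND6, rose (the same adjusted over the list alone; median 0.05, 0.28 with quantile normalization and 0.02 with the GC and length correction), from 239 ± 30.7 to 359 ± 22.5 FPKM, a call not made without FOXK2 replicate 3 (adjusted p = 0.0514). After correction for GC content and length, 7 angiogenic factors rose and 5 fell, 1 hypoxia-inducible gene rose and 8 fell, 2 glycolysis genes rose and 4 fell, and 4 nuclear genes of oxidative phosphorylation fell with none rising.

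Signalling lists were also mixed. Of 21 genes of MAPK/ERK output 4 rose and 1 fell (3 and 1 adjusted over the list alone, median 0.31), and the feedback inhibitor SPRY4 rose from 5.56 ± 0.536 to 13.2 ± 1.18 FPKM, with SPRY2 at a log2 fold change of 0.75. Of 17 components of the PI3K/AKT/mTOR pathway 3 rose and 1 fell (the same adjusted over the list alone; median 0.24, 0.09 with the GC and length correction), among them PIK3R1, the gene of the p85alpha regulatory subunit, from 0.588 ± 0.362 to 3.61 ± 1.44 FPKM. FOXO target genes had 1 of 14 members higher and 5 lower (1 and 6 adjusted over the list alone; median -0.15, -0.29 with the GC and length correction), with FBXO32 falling from 3.95 ± 0.232 to 0.263 ± 0.0981 FPKM and CITED2 from 12.1 ± 2.31 to 2.32 ± 0.0953 FPKM, while KLF6 rose with a log2 fold change of 0.82. Genes of FOXK2 partner proteins had 2 of 18 members higher and none lower (the same adjusted over the list alone, median 0.15). The corepressor NCOR1 rose from 24.1 ± 3.57 to 52.0 ± 11.7 FPKM, a call not made with its most abundant transcript (adjusted p = 0.174). Among 12 receptor tyrosine kinases 1 rose and 1 fell (the same adjusted over the list alone; median -0.19, -0.12 with the GC and length correction). MET stood at 24.9 ± 9.02 and 53.5 ± 7.58 FPKM (log2 fold change 1.13, limma adjusted p = 0.0175), which was not called without FOXK2 replicate 1 (1.04, adjusted p = 0.0557) or replicate 3 (1.11, adjusted p = 0.0545) or with its most abundant transcript (2.01, adjusted p = 0.212). YAP/TAZ target genes had 2 of 17 members higher and 5 lower (3 and 6 adjusted over the list alone; median -0.07, -0.01 with the GC and length correction), with the kinase gene NUAK2 falling from 7.08 ± 0.732 to 1.52 ± 0.776 FPKM and tissue factor (F3) rising from 5.75 ± 0.576 to 12.2 ± 1.40 FPKM. Of 5 Wnt target genes 1 rose and none fell (the same adjusted over the list alone, median 0.14), the Wnt antagonist DKK1, from 5.62 ± 0.157 to 10.2 ± 0.336 FPKM. In the fit corrected for GC content and length 9 genes of MAPK/ERK output rose and 1 fell, 3 receptor tyrosine kinases rose and 1 fell, and 4 YAP/TAZ target genes rose and 5 fell.

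Among genes of stress and cell survival, 10 of 25 autophagy and lysosome genes fell and 2 rose (11 and 2 adjusted over the list alone, median -0.31). The autophagy receptor SQSTM1 fell from 283 ± 42.7 to 110 ± 17.8 FPKM, ULK1, a kinase that starts autophagy, from 7.70 ± 0.918 to 3.08 ± 0.193 FPKM and cathepsin D (CTSD) from 52.5 ± 3.47 to 23.3 ± 2.82 FPKM. With the GC and length correction this list passed camera at the preset correlation (median -0.42, adjusted p = 0.0106), as did MAPK/ERK output (0.34, adjusted p = 0.0382) and the immediate-early and heat shock genes (0.60, adjusted p = 0.00378). At an estimated correlation none of these 3 passed (adjusted p = 0.190, 0.274 and 0.190). The last list had 5 of 14 members higher and 1 lower without the correction (6 and 1 adjusted over the list alone, median 0.32). In it the chaperone HSP90AA1 rose from 495 ± 51.8 to 1126 ± 115 FPKM and JUN from 27.9 ± 0.684 to 52.6 ± 1.84 FPKM, while JUNB fell from 32.6 ± 3.54 to 13 ± 2.84 FPKM. Apoptosis regulators had 3 of 20 members higher and 5 lower (3 and 6 adjusted over the list alone, median -0.22), with BIRC3, an inhibitor of apoptosis and NF-kB target, falling from 2.87 ± 0.556 to 0.447 ± 0.210 FPKM and the pro-apoptotic genes BIK and BID falling with log2 fold changes of -1.35 and -0.94. Of 12 p53 target genes none rose and 1, TP53I3, fell (the same adjusted over the list alone; median -0.12, 0.15 with the GC and length correction), from 14.1 ± 3.01 to 6.20 ± 2.09 FPKM, a call not made with its most abundant transcript (adjusted p = 0.0533). The unfolded protein response list had 4 of 17 members higher and 3 lower (5 and 3 adjusted over the list alone; median 0.24, 0.09 with the GC and length correction). Its chaperone HSP90B1 stood at 157 ± 21.6 and 284 ± 68.9 FPKM (log2 fold change 0.83, limma adjusted p = 0.0171), not called without vector replicate 3 (0.71, adjusted p = 0.0595) or FOXK2 replicate 3 (0.78, adjusted p = 0.0605). In that corrected fit 8 immediate-early and heat shock genes rose and 1 fell, 5 apoptosis regulators fell with none rising, and 4 genes of the unfolded protein response rose and 1 fell.

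In metabolism, 4 of 17 genes of the ATF4 and amino acid response rose and 1 fell (the same adjusted over the list alone). ASNS, asparagine synthetase, rose from 21.4 ± 2.98 to 69.5 ± 13 FPKM, PSAT1, of serine synthesis, from 30.7 ± 1.76 to 64.0 ± 6.29 FPKM, and CEBPB fell from 28 ± 4.65 to 10.1 ± 1.55 FPKM. The median of this list was -0.05 (-0.09 with quantile normalization and 0.21 with the GC and length correction), while its mean was 0.09 and the direction of its test was up. Of 19 cholesterol synthesis genes 5 rose and 2 fell (the same adjusted over the list alone; median 0.23, 0.09 with the GC and length correction), and HMGCS1 stood at 5.01 ± 0.897 and 15.0 ± 4.67 FPKM (log2 fold change 1.38, limma adjusted p = 0.00522; 0.91, adjusted p = 0.0625 with the GC and length correction). NRF2 target genes had 2 of 14 members higher and 5 lower (the same adjusted over the list alone; median -0.46, -0.17 with the GC and length correction), and the ferritin genes FTL and FTH1 fell from 634 ± 73.1 and 655 ± 37.3 to 253 ± 46.3 and 278 ± 72.8 FPKM. Of 6 drug efflux transporters and related genes 1 rose and 2 fell (1 and 3 adjusted over the list alone, median -0.81): ABCC4 rose from 3.07 ± 0.489 to 7.17 ± 0.992 FPKM, ABCC3 fell from 5.00 ± 1.59 to 0.573 ± 0.142 FPKM and MVP fell from 47.9 ± 2.79 to 18.2 ± 2.74 FPKM, MVP not being called with its most abundant transcript (adjusted p = 0.0550). Of 12 replication-dependent histone genes none rose and 5 fell (the same adjusted over the list alone; median -0.09, 0.40 with the GC and length correction, where 5 rose and 2 fell), with HIST1H2AC falling from 17.3 ± 4.50 to 4.04 ± 1.25 FPKM. With that correction 2 cholesterol synthesis genes rose and 1 fell, and 5 NRF2 target genes fell with none rising.

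Lineage and matrix markers changed in part. Of 12 epithelial markers 1 rose and 3 fell (2 and 4 adjusted over the list alone; median -0.07, 0.07 with quantile normalization and 0.04 with the GC and length correction). Keratin 19 (KRT19) fell from 621 ± 11.6 to 251 ± 34.5 FPKM and the tight junction gene CLDN1 from 31.2 ± 3.02 to 12.9 ± 2.13 FPKM. Mesenchymal markers had 2 of 17 members higher and 1 lower (the same adjusted over the list alone, median 0.15), with TGFBI falling from 13.4 ± 1.6 to 5.31 ± 0.811 FPKM and ITGB1 at 154 ± 25.6 and 288 ± 52.8 FPKM (log2 fold change 0.90, limma adjusted p = 0.00936; not called with its most abundant transcript, adjusted p = 0.0917). Extracellular matrix genes had 2 of 18 members higher and 5 lower (the same adjusted over the list alone), with tenascin C (TNC) falling from 72.9 ± 7.07 to 33.7 ± 4.05 FPKM and versican (VCAN) rising from 3.17 ± 0.628 to 7.91 ± 1.43 FPKM. The median of that list was 0.02 (-0.14 with the GC and length correction), while its mean was -0.15 and the direction of its test was down. With the correction 7 mesenchymal markers rose and 3 fell (median 0.38), and 4 extracellular matrix genes rose and 5 fell. Of 19 thyroid differentiation genes 2 were measured: HHEX rose from 20.0 ± 1.99 to 49.5 ± 5.06 FPKM, and PAX8 stood at 121 ± 32.3 and 102 ± 16.7 FPKM (log2 fold change -0.23, limma adjusted p = 0.410; 0.22, adjusted p = 0.478 with the GC and length correction), with the same calls adjusted over the list alone.

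Markers of other cell types were few. None of 10 endothelial markers was listed. Of 14 immune cell markers 2 were measured and neither passed, over all genes or adjusted over the list alone: CD68 stood at 17.0 ± 3.56 and 12.7 ± 1.61 FPKM, and LYZ at 0.182 ± 0.129 FPKM in vector cells and at 0.204, 21.6 and 0.167 FPKM in FOXK2 replicates 1, 2 and 3. Of 10 fibroblast markers 2 were measured, the collagen genes COL1A1 and COL1A2, which fell over all genes and adjusted over the list alone. COL1A2 fell from 7.14 ± 0.976 to 2.48 ± 0.191 FPKM, and COL1A1 stood at 28.1 ± 3.72 and 18.2 ± 0.886 FPKM (log2 fold change -0.59, limma adjusted p = 0.0159), not being called without vector replicate 1 (-0.51, adjusted p = 0.0552) or 2 (-0.57, adjusted p = 0.0580) or with the GC and length correction (-0.29, adjusted p = 0.105).

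At the level of transcripts, 1577 of 21342 tested differed, 646 higher and 931 lower in FOXK2 cells. Of 5351 genes with at least 2 tested transcripts, 17 had transcripts called in opposite directions. In LRRC8A, a subunit of volume-regulated anion channels, ENST00000259324 fell from 26.4 ± 1.41 to 0.0105 ± 0.0112 FPKM while ENST00000372600 rose from 3.27 ± 2.06 to 23.0 ± 4.61 FPKM. In FKBP8, ENST00000222308 fell from 45.6 ± 4.41 to 18.1 ± 1.98 FPKM and ENST00000544835 rose from 2.06 ± 1.13 to 21.0 ± 4.38 FPKM. In MAPK8IP1, ENST00000241014 had a vector mean of 10.5 FPKM and was listed at 0 in every FOXK2 library, and ENST00000395629 was listed at 0 in every vector library and had a mean of 6.27 FPKM in FOXK2 cells. In UHRF1, ENST00000615884 rose from 5.45 ± 3.17 to 30.0 ± 2.45 FPKM, and ENST00000616255 had a vector mean of 2.97 FPKM and was listed at 0 in every FOXK2 library. The division of reads between transcripts is the estimate made before deposition, and its error is unknown. The number of transcripts called was 361, 176 and 293 without vector replicates 1, 2 and 3, and 408, 2168 and 292 without FOXK2 replicates 1, 2 and 3. It was 4009 with array weights and 22 with the replicate number as a block.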

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

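The GC and length correction was chosen after seeing the data, and the other alternatives before. The requirement of a log2 fold change of at least 1 was run only for the counts of genes and transcripts. FOXK2 (0.998) and VEGFA (0.718) lie under it in the main fit and would not be called. They kept their direction and call under the other alternatives, except VEGFA with the most abundant transcript in place of the gene sum (log2 fold change 0.715, adjusted p = 0.0694; VEGFA's adjusted p was at most 0.0474 otherwise). That setting called 2143 genes, 960 higher and 1183 lower. The sign was opposite there for RPS6KB1 (-0.183), CRELD2 (0.348) and DNAJB11 (-0.0803), none past the threshold there, and the cause was not tested. Array weights called 7117 genes (3615 higher, 3502 lower) and 4009 transcripts (1838 higher, 2171 lower). Their gene-level estimation stopped before convergence with a weight of 29.2 on FOXK2 replicate 3, so the mean of the FOXK2 group rests mostly on that library there. Requiring a log2 fold change of at least 1 left 1040 genes (458 higher, 582 lower) and 1074 transcripts (423 higher, 651 lower). The smaller counts follow by construction of the threshold.

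Leaving out 1 library gave 1944 to 4767 genes (850 to 2374 higher, 1094 to 2393 lower) and 176 to 2168 transcripts (65 to 909 higher, 111 to 1259 lower). Gene counts moved by over 1.5 times without vector replicate 2 (2289) or 3 (2018) or FOXK2 replicate 1 (2349) or 3 (1944), where fewer samples entered the fit, while leaving out FOXK2 replicate 2 gave the highest count. No gene called with all libraries was called in the opposite direction in any of these fits. The camera count of 4 lists was the same in each.

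Of the lists, 1 passed with an estimated correlation and 7 with the GC and length correction, none of which passed with the correction and an estimated correlation together. The causes were not tested. In the sample titles the replicates share only a number. Deviations of same-numbered samples correlated at 0.126, -0.168 and -0.0564 across genes, and not every sample correlated best with its own number. Whether same-numbered samples were handled together cannot be told from these values. With a replicate block, 2982 genes, 22 transcripts (5 higher, 17 lower) and 4 lists were called. Over 143 named genes and up to 17 alternatives, 2252 of 2405 values stayed on their side of the threshold, 10 of these with the opposite sign and past the threshold in neither fit. The others were 122 that lost the call, 28 that gained one and the 3 of opposite sign above. In 91 of these genes none of these alternatives changed the call. Read depth is unknown, so what counting error limits was not assessed.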

Other observations

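Further gene groups were chosen after the results had been seen, so their tests are not independent evidence. Of 16 genes of MHC class I antigen presentation 10 were lower in FOXK2 cells and none higher (median log2 fold change -1.02; adjusted p = 0.0578 with an estimated correlation). The immunoproteasome subunit genes PSMB9 and PSMB10 fell from 25.3 ± 0.859 and 15.6 ± 1.97 to 4.35 ± 1.52 and 1.80 ± 0.690 FPKM (SD of 3 libraries), and the peptide transporter TAP1 from 19.5 ± 1.28 to 5.94 ± 1.30 FPKM. Complement and acute-phase genes fell in 7 of 8 measured members (median -3.65; adjusted p = 0.0131 with an estimated correlation), with PTX3 going from 56.4 ± 1.71 to 5.62 ± 0.341 FPKM. Of 3 measured BMP and ID genes, ID1 fell from 316 ± 43.9 to 38.1 ± 8.67 FPKM and ID3 from 30.0 ± 6.48 to 2.50 ± 1.15 FPKM, while HEY1 did not pass. Of 4 measured metallothioneins 3 fell, and MT2A did so only without the GC and length correction (log2 fold change -0.68, corrected 0.06).

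On the rising side, 15 of 18 kinesin motor genes rose and none fell (median 1.38; adjusted p = 0.0578 with an estimated correlation). KIF11, KIF20A and KIF4A, motors of the mitotic spindle and of cytokinesis, had log2 fold changes of 2.05, 2.00 and 2.00. Of 19 measured centromere and kinetochore genes 15 rose and none fell (median 1.16; adjusted p = 0.0281 with an estimated correlation), among them CENPF, NUF2 and NDC80 with log2 fold changes of 2.11, 1.76 and 1.70. With the GC and length correction 14 kinesin genes were higher and 1 lower, and 14 centromere and kinetochore genes were higher.

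The counts over splits of the samples below were planned before the results were seen, and every other test below was chosen after. Of the 10 splits of the 6 libraries into 3 and 3, 1, the real one, gave as many genes (3741, against at most 2 in another split) and 1 as many transcripts (1577, against at most 13). As many lists as the real split's 4 were given by 8 of the 10 splits, with up to 7 in another. The number of lists called therefore does not set the real split apart. Every other split mixed libraries of both groups unevenly, so part of the group difference stayed in its contrast and part entered its spread. Such splits are not a reference free of that difference, for lists, genes or transcripts. For genes and transcripts, the splits are too few for a share under 0.05.

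The fall of NF-kB-driven cytokines and of interferon-stimulated genes was weighed against the GC and length trend. After the correction the list medians were -3.09 (95% bootstrap interval over genes -4.31 to -2.11) and -1.13 (-1.34 to -0.863), so the trend does not account for either fall. A difference in culture density was examined through the YAP/TAZ target genes, whose median of -0.0730 (-0.510 to 0.311) lies over members that moved both ways and leaves density open. An effect of FOXK2 and other differences between the 2 kinds of culture were not tested against each other and stay open.

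The rise of DNA replication and mitosis genes was tested in the same way. Its corrected median was 1.07 (0.658 to 1.39), so the GC and length trend does not account for it. An effect of FOXK2 and the growth state of the cultures at harvest, which is not given in the labels, were not tested against each other and stay open.

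The lower level of GC-rich genes in FOXK2 libraries is the third pattern. The fall of ribosomal protein genes (median -0.415) may follow from the GC and length trend, since the corrected median was -0.0722 (-0.181 to 0.0961). Their median GC content of 51.5% was not high: genes in the bin with a median of 51.1% had a median log2 fold change of -0.0454. Their median length was 971 bases, and the parts of the correction for GC content and for length were not separated. The trend may also place FOXK2 replicate 2 nearer the vector libraries: each FOXK2 library was placed on its own axis, with 0 at the vector mean and 1 at the mean of the other 2 FOXK2 libraries. Replicate 2 lay at 0.659 before and 0.805 after the correction, and its gap to the next FOXK2 library was 0.276 and 0.0729. That gap compares positions on different axes, so it is not a distance along either of them. Vector RNA or cells mixed into that library are argued against by 19 genes that fell at least 8-fold in the other FOXK2 libraries, whose median share of the way back to the vector level was -4.48e-05 (-0.00626 to 0.0161). Library-to-library variation in GC recovery and an effect of FOXK2 cannot be told apart. Every FOXK2 library had a lower GC slope than every vector library, so the trend follows the groups. The slope also varied between libraries of a group: its largest range within a group was 0.884 times the difference between the group means (0.334 against 0.378).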
